A study of Homo sapiens with 2 samples.

How the data were processed

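Gene expression was measured in 2 samples of MCF-7 cells, 1 per group, on 1-colour (Cy3) Agilent arrays of 62976 spots. Groups were taken from the sample titles. Both arrays lay on 1 slide and were scanned on 1 day, per the file headers, so that slide and day did not differ between the groups.

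The deposited values are the scanner software's output for each spot. Per the file headers, Agilent Feature Extraction 10.10.1.1 computed the intensity by subtracting a spatially fitted background and applying a multiplicative detrending within each array, with no normalization between arrays. Per the file headers it also gave an error of each intensity (about 10% of a bright signal) and flags of 0 or 1 for spots well above background, saturated spots and outlier spots. The authors' value table held the same intensities in its 62976 rows, so it served as an unscaled alternative. Background subtraction makes dim signals noisy, and scaling between arrays assumes that the upper part of the signal distribution is alike in both.

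The main value was log2 of the processed intensity minus the 75th percentile of it over the 58717 non-control spots of each array, and the difference was siDYRK2 minus siControl. Control spots (4259 per array) and outlier-flagged spots were left out: non-uniform spots numbered 7 on siDYRK2 and 14 on siControl, and population outliers 344 and 318. Spots of a probe were averaged, and a probe counted as detected when over 50 percent of its spots were well above background. A gene was the mean over its probes detected and unsaturated on both arrays, which held for 27411 of 50599 probes and 20662 genes, 4964 of them with several probes. The scanner error was averaged over the spots of a probe, propagated to the probe's difference between the arrays, and averaged over a gene's probes. It is thus an error of a typical single spot, not reduced by replicate spots or probes, and holds no spread between probes. Over the 676 probes with at least 5 replicate spots, the median SD of the difference between spots was 0.063. Printed intensities are before scaling, as the mean over a gene's measured probes. These errors are technical. The number of arrays, 1 per group, limits the precision, and no test between the conditions was possible.

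Probes were named through a RefSeq table of the assembly GRCh38, used for names and gene classes only: 28174 probes matched by accession, 2618 by symbol and 620 by synonym, and 19187 kept the name in the files. Coordinates are those of the files, on GRCh37 (hg19). No genome sequence was used, so the part of a transcript that a probe reads is not given.

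Genes were counted at a fixed size of 2-fold, and members of lists at 1.5-fold. The lists covered the kinase family and its partners, stem-like genes, cell cycle, MYC, AP-1, p53, epithelial, mesenchymal, oestrogen, luminal, basal, Hedgehog, Wnt, interferon, NF-kB, stress, metabolic, ribosomal, histone, apoptosis, mTOR, silencing-machinery and housekeeping genes, and markers of fibroblasts, immune and endothelial cells. These 34 lists, the naming rule, the main settings and the alternatives were fixed before the data were examined. Each list's median was placed among those of 10000 random lists of the same size, drawn from measured protein-coding genes outside the list and matched on mean expression in 20 bins. A median below percentile 2.5 or above 97.5 was called outside the range, and lists with fewer than 5 measured members got no percentile. Further lists, chosen after values had been seen, are reported under the other observations.

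Named genes were DYRK2, and the up to 10 highest and 10 lowest genes with a symbol, at least median signal, a difference of at least 2-fold and all measured probes on the same side of 0. Also named were up to 2 members at each end of a list, 10 genes of prior interest, and the 3 genes per array with the largest bound among genes detected on 1 array only.

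Alternatives were normexp background correction (offset 50, limma 3.58.1 in R 4.3.3), scaling by quantiles, by the median, by the 75th percentile of detected probes, by loess (span 0.3) and by spike-in RNA, the unscaled values, no filter on dim probes, brighter probes only, outlier spots kept, the brightest probe or the median over probes, thresholds of 1.5-fold and 3-fold, 10 or 50 bins, lists without shared members, and another detection call. A list median counted as moved when it shifted, relative to the shift of the genes shared with the main setting, by more than the replicate-spot SD; this reference to shared genes was set after a first version had marked every list as moved when the filter on dim probes was lifted. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

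The counting was tested on simulated data for the comparison of siDYRK2 with siControl over 20662 genes: 98% of simulated 3-fold changes and 0% of 1.5-fold changes were called at 2-fold, with 13 unchanged genes called. The simulated array was the control array plus noise of the size of the scanner error, with no spread between cultures. The 13 are therefore no false-positive count for the real comparison. For lists of 20 genes, drawn from 13973, 5% of unchanged lists, 40% of those shifted by 0.1 and 95% of those shifted by 0.2 were called outside the range. Differences were shuffled there among genes of like expression, so members did not vary together as genes of real lists may.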

Results

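RNA levels were measured in MCF-7, an established oestrogen receptor-positive breast cancer cell line, after transfection with a small interfering RNA (siRNA). Total RNA from cells given an siRNA against DYRK2, a protein kinase, was hybridised to 1 one-colour Agilent array (siDYRK2), and RNA from cells given a non-silencing siRNA to another (siControl). Each group thus had 1 array, differences had no replicate check, and no p-value was computed. The ± values are errors from the scanner software and hold none of the spread between cultures. On the array labelled siDYRK2, 58.8% of 58717 non-control spots lay well above background, against 59.5% on the array labelled siControl, and no spot was saturated. The 75th percentile of intensity, to which each array was scaled, was 1019 and 1082. Signals of 20662 genes, 13973 of them protein coding, were measured on both arrays. Across genes, which are not independent replicates, their log2 levels had a Pearson correlation of 0.996.

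The targeted gene was examined first, since it checks the labels. DYRK2 was not lower on the array labelled siDYRK2 by more than the scanner error. Its single probe, at bases 68056135 to 68056194 of chromosome 12 (GRCh37, on the transcript NM_006482; the part of the transcript it lies in was not given in the files), had an intensity of 2376 there and 2576 on the array labelled siControl. After scaling, the log2 difference was -0.031 ± 0.20. Scaled to spike-in RNA, which put the median of all genes 0.28 lower, it was -0.31, beyond the scanner error but short of 1.5-fold. The label therefore had no check from its own target, and "the array labelled siDYRK2" is written throughout. Every direction given here is that array minus the array labelled siControl.

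The comparison asked which transcripts differed between DYRK2-targeted and control MCF-7 cells. Among genes of at least median signal, several genes induced by interferon stood at the upper end. IFI27 was 5.06-fold higher on the array labelled siDYRK2 (log2 difference 2.34 ± 0.20), IFI6 4.79-fold (2.26 ± 0.20) and IFIT1 3.87-fold (1.95 ± 0.20). OLFM4, which is not on the interferon list, lay between IFI6 and IFIT1 at 4.68-fold, and some dimmer genes lay above IFI27. NF-kB and inflammatory genes were higher as a group, and replication-dependent histone genes and mitotic genes were slightly higher as groups, a direction that turned when scaled to spike-in RNA (medians of -0.069 and -0.13). Targets of the tumour suppressor p53 were lower as a group, with the death receptor gene FAS 2.44-fold lower (-1.29 ± 0.22). Collagen I transcripts were higher, with COL1A1 at 3.59-fold (1.84 ± 0.21). These are differences between 2 arrays.

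In all, 98 genes (0.474%) were at least 2-fold higher on the array labelled siDYRK2 and 46 (0.223%) at least 2-fold lower. Among protein-coding genes the counts were 62 and 21. The counts depended on processing, being 30 and 9 with normexp background correction, 46 and 162 when scaled to spike-in RNA, and 1427 and 887 with no filter on background. Dim genes made up most of both counts: of equal groups of genes ordered by signal, the dimmest 5166 held 61 higher and 29 lower genes and the brightest 5166 held 6 and 0, while the SD of the differences went from 0.39 to 0.19. The higher genes were 68.1% of these calls, a share that depended on scaling: it was 58.04% after quantile normalization, 56.7% after loess, 55.1% with median scaling, 55.4% unscaled and 22.1% when scaled to spike-in RNA, and 76.9% with normexp background correction.

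**Figure D1:**
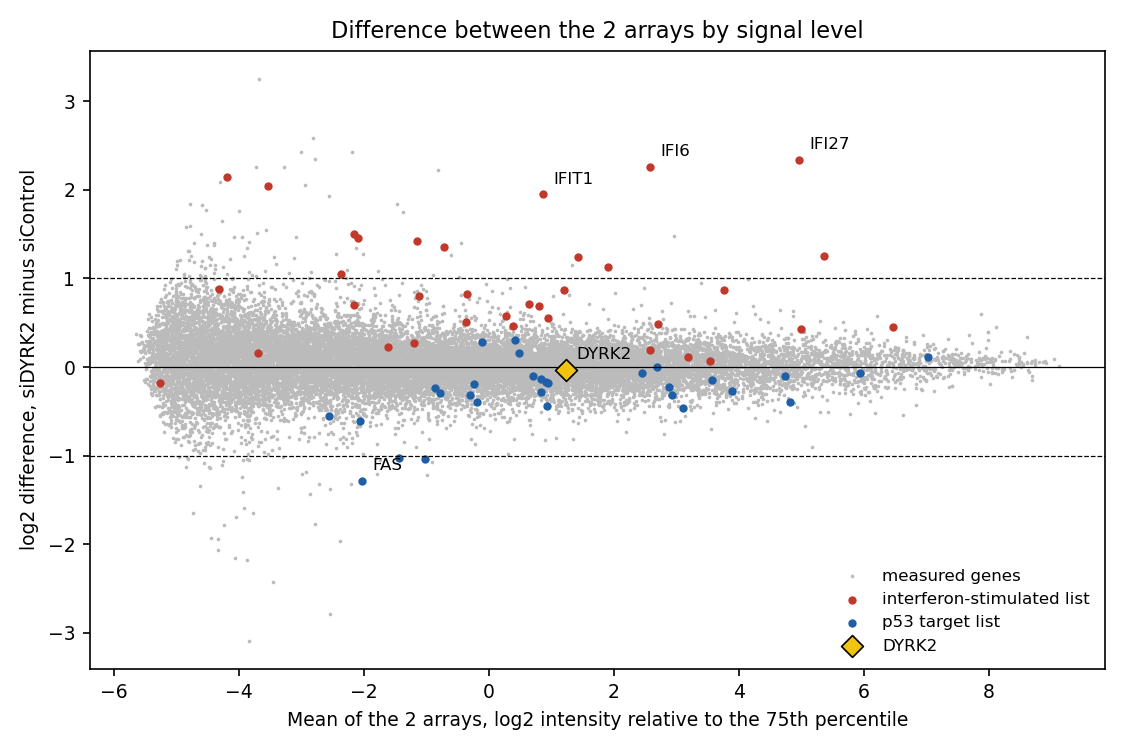
Each point is 1 of the 20662 measured genes, with the mean log2 intensity of the 2 arrays relative to the 75th percentile on the x axis and the log2 difference, siDYRK2 minus siControl, on the y axis; dashed lines mark 2-fold. Members of the interferon-stimulated list (red) reach 2.34 (IFI27), p53 target genes (blue) reach -1.29 (FAS), and DYRK2 (diamond) lies at -0.031.

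Among genes of at least median signal, 13 passed the rule for naming higher genes, and the 10 highest are named. After IFI27 (intensity 71231 against 14948; chromosome 14, bases 94582967 to 94583026) and IFI6 (13329 against 2954; chromosome 1, bases 27992837 to 27992896) came OLFM4, encoding the secreted glycoprotein olfactomedin 4, at 4.68-fold (2.23 ± 0.21; chromosome 13, bases 53626095 to 53626154). IFIT1 (chromosome 10, bases 91163438 to 91163497) was followed by SLC25A25, a mitochondrial ATP-magnesium/phosphate carrier gene, at 2.79-fold (1.48 ± 0.20), and by the small Cajal body RNA SCARNA20 at 2.65-fold (1.40 ± 0.20). The antiviral GTPase gene MX1 was 2.55-fold higher (1.35 ± 0.20). PIP, the prolactin-induced protein gene of apocrine breast cells, was 2.40-fold higher (1.27 ± 0.20). The ubiquitin-like modifier gene ISG15 was 2.39-fold higher (1.26 ± 0.20), and IRF9, the DNA-binding part of the interferon-activated ISGF3 complex, 2.37-fold (1.24 ± 0.20). Each of these 10 genes was read by 1 probe. Scaled to spike-in RNA, which lowered every difference alike, PIP (0.98), ISG15 (0.97) and IRF9 (0.96) fell short of 2-fold.

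At the lower end, 3 genes passed the same rule. NKIRAS1, an inhibitor of NF-kB signalling, was 2.32-fold lower (log2 difference -1.22 ± 0.21; chromosome 3, bases 23934657 to 23934716). EDA2R, the ectodysplasin A2 receptor gene, was 2.10-fold lower (-1.07 ± 0.21; chromosome X, bases 65815490 to 65815549). TIGAR (C12orf5 on the array), encoding a fructose bisphosphatase, was 2.06-fold lower (-1.04 ± 0.21; chromosome 12, bases 4469058 to 4469117). With normexp background correction EDA2R and TIGAR stood at -0.95 and -0.91, short of 2-fold, and with no filter on background EDA2R stood at -0.75.

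The 34 gene lists fixed before the data were examined were set against random lists of the same size and expression. Of the 32 lists with at least 5 measured members, 9 had a median above and 2 a median below the central range of the random medians, where about 1.6 would lie outside by chance. Genes of a list are often expressed together, so these percentiles describe the 2 arrays only.

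**Figure D2:**
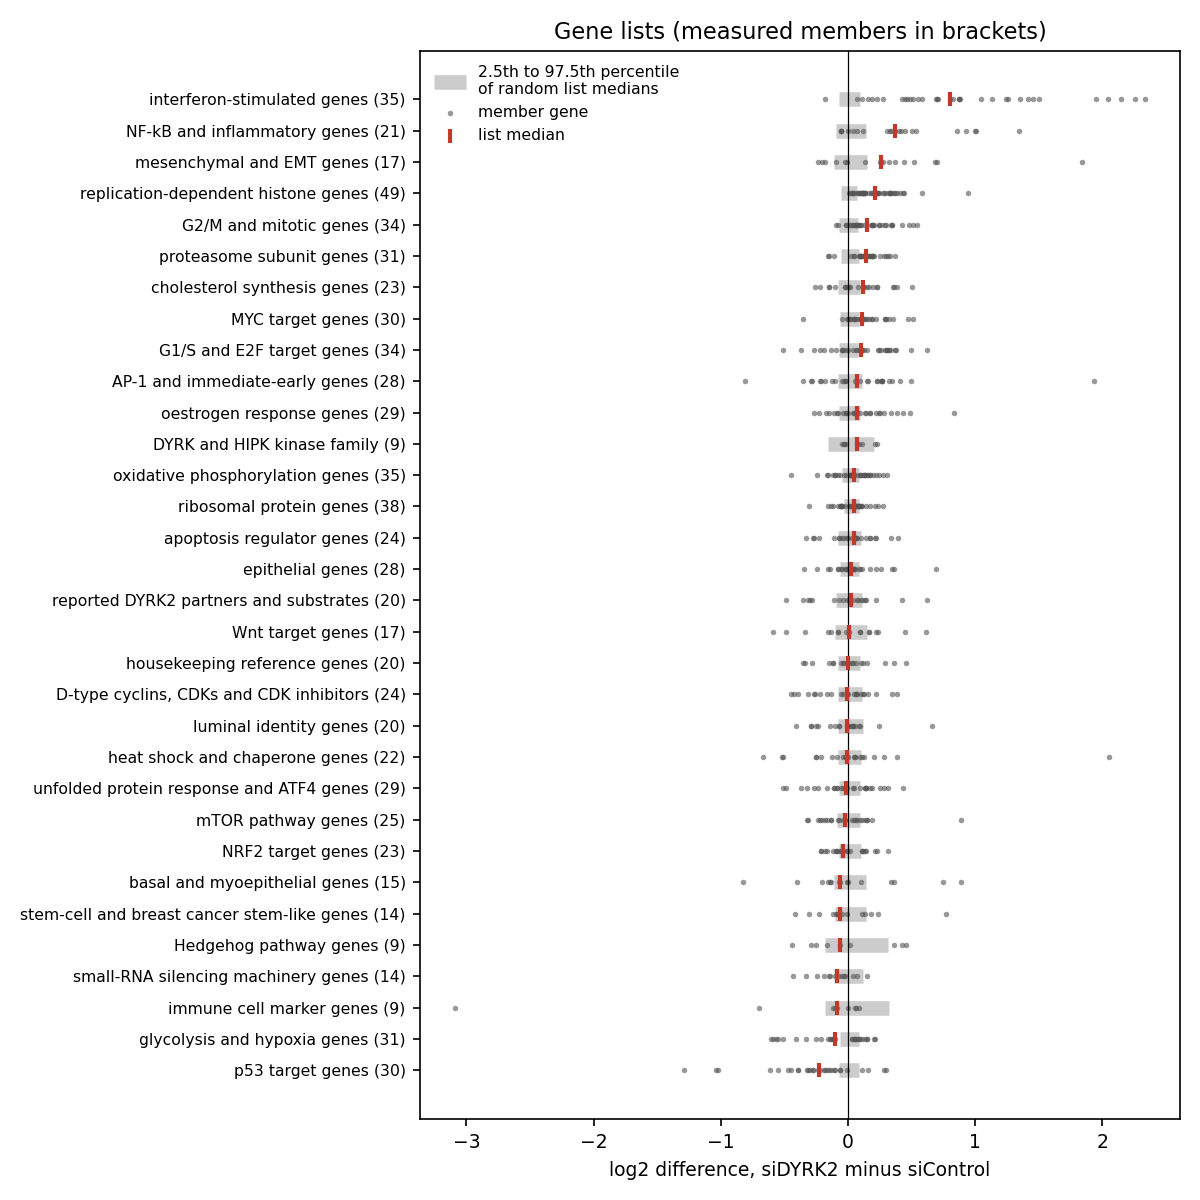
For each of the 32 lists with a percentile, points show the log2 difference (x axis, siDYRK2 minus siControl) of each measured member, the red bar the list median, and the grey band the central range (95%) of 10000 random list medians. The interferon-stimulated median lies at 0.81 and the p53 target median at -0.23, both outside their bands.

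Interferon-stimulated genes had the highest median of the lists with a percentile. Of 35 measured members of 40, 34 were above 0 and 21 were at least 1.5-fold higher, with none that much lower; the median difference was 0.81, at percentile 100. They made up 13 of the 98 genes at least 2-fold higher, and 7 of the 14 such genes of at least median signal. Beside IFI27 and IFI6, the lowest members were USP18 (0.072 ± 0.20) and SAMD9, a dim gene (-0.18 ± 0.39). The list's median stayed above 0.5 under the alternatives tried, the lowest value being 0.53.

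NF-kB and inflammatory genes had a median of 0.37, at percentile 100. Scaled to spike-in RNA, which lowered every difference alike and so could not change the percentile, the median was 0.090. Of 21 measured members of 26, 18 were above 0 and 5 were at least 1.5-fold higher. The neutrophil-attracting chemokine genes CXCL1 (2.54-fold; 1.35 ± 0.22, its 2 probes at 1.06 and 1.64) and CXCL8 (2.01-fold; 1.01 ± 0.25) were the highest. NFKB1, encoding the p105 precursor (-0.058 ± 0.20), and the cytokine gene LIF (-0.053 ± 0.21) were the lowest. CXCL8 rested on its 1 probe above background: with dim probes included it turned to -0.38, and with normexp it stood at 0.52.

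Of the 30 measured p53 target genes, 26 were below 0. Their median was -0.23, at percentile 0.00 of the random lists, and 4 members were at least 1.5-fold lower. FAS was read by 3 probes between -1.31 and -1.24 (its brightest at chromosome 10, bases 90774545 to 90774604), and TIGAR was next. AEN (0.30 ± 0.20), a nuclease gene, and TP53I3 (0.29 ± 0.20), an oxidoreductase gene, were the highest members. CDKN1A, the p21 cell-cycle inhibitor gene, stood at -0.39 ± 0.20. With normexp FAS stood at -0.95, while the list's median stayed between -0.51 and -0.19 under the alternatives.

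Several cell-cycle and growth lists were shifted up by small amounts. All 49 replication-dependent histone genes were above 0, with a median of 0.21 at percentile 100; H4C8 (HIST1H4H on the array) stood at 0.94 ± 0.20 and H4C9 (HIST1H4I) at 0.58 ± 0.20, H2AC8 (HIST1H2AE) at 0.021 ± 0.20 and H2BC12 (HIST1H2BK) at 0.0076 ± 0.20, its 2 probes at -0.14 and 0.15. These genes are near-identical copies whose probes may share targets, so single members are uncertain. Of 34 genes of the G2 and M phases, 30 were above 0, with a median of 0.15 at percentile 100 and no member past 1.5-fold. The mitotic kinase gene AURKB (0.54 ± 0.20) and the cyclin F gene CCNF (0.51 ± 0.21) were the highest, and KIF11 (-0.095 ± 0.20) and NUSAP1 (-0.077 ± 0.20), both of the mitotic spindle, the lowest. Of 34 G1/S and E2F target genes, 23 were above 0, with a median of 0.10 at percentile 99.4. The phosphatase gene CDC25A was 1.54-fold higher (0.62 ± 0.20) and the kinase gene CDK2 stood at 0.50 ± 0.21, whereas the nucleotide synthesis genes TYMS (-0.37 ± 0.20) and RRM2 (-0.51 ± 0.27, its 3 probes from -1.25 to 0.19, the brightest at 0.19) lay below 0. MYC target genes had 27 of 30 members above 0 and a median of 0.11 at percentile 99.4, from EIF5A (0.51 ± 0.20) and PPAN (0.47 ± 0.20) to RRP9 (-0.043 ± 0.20) and TFRC (-0.35 ± 0.20). Proteasome subunit genes had 28 of 31 above 0 and a median of 0.14 at percentile 99.99, with PSMA7 (0.37 ± 0.20) and PSMA4 (0.33 ± 0.20) the highest and PSMA1 (-0.16 ± 0.21, its 2 probes at -0.35 and 0.025) and PSMC2 (-0.15 ± 0.20, its 2 probes at -0.41 and 0.11) the lowest; both lay above 0 when read by the brightest probe. Cholesterol synthesis genes had 15 of 23 above 0 and a median of 0.12 at percentile 99.3, with ACAT2 (0.51 ± 0.20) and TM7SF2 (0.39 ± 0.20) above INSIG1 (-0.26 ± 0.20) and HMGCR (-0.22 ± 0.20). The medians of these 6 lists are relative to the 75th percentile: scaled to the spike-in RNA, which put the median of all genes 0.28 lower, the 6 lay below 0, between -0.18 and -0.069. Their place among random lists could not change, as all differences moved alike.

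Mesenchymal and EMT genes had a median of 0.26, at percentile 99.99, with 11 of 17 measured members above 0 and 3 at least 1.5-fold higher; scaled to spike-in RNA the median was -0.020. COL1A1, a collagen I chain gene, was the highest (intensity 695 against 206), followed by the N-cadherin gene CDH2 (0.70 ± 0.22, or 1.33 with no filter on background). SPARC (-0.23 ± 0.32) and the collagen V gene COL5A1 (-0.21 ± 0.21, its 2 probes at -0.60 and 0.18) were the lowest. Markers of fibroblasts, a cell type that the culture should not hold, moved the same way: 5 of 12 were well above background on the array labelled siDYRK2 and 2 on the array labelled siControl, and the 2 measured on both were COL1A1 and the growth factor receptor gene PDGFRA (1.40 ± 0.31, or 0.71 with normexp), with a median of 1.62.

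Glycolysis and hypoxia genes had a median of -0.10, at percentile 0.16, although 15 of 31 members were above 0. NDRG1 (1.52-fold lower; -0.60 ± 0.20) and PFKFB4 (-0.59 ± 0.20) were the lowest, ADM (0.21 ± 0.20) and TPI1 (0.20 ± 0.20) the highest. The place outside the random range was lost in 5 alternatives, among them normexp (median -0.031, percentile 15.1), and turned to 0.031 among brighter probes.

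For the other 21 lists with a percentile the median lay within the random range. Among lists tied to the kinase, the DYRK and HIPK kinase family had a median of 0.069 (percentile 69.0; HIPK2 0.23 ± 0.21 with 5 probes from -0.036 to 0.59, DYRK3 0.21 ± 0.27, DYRK1B -0.047 ± 0.20, HIPK3 -0.031 ± 0.21), and reported DYRK2 partners and substrates 0.025 (percentile 58.7; CDC25A the highest, then GLI2 at 0.42 ± 0.34, with MYC -0.49 ± 0.20 and JUN -0.35 ± 0.20 the lowest). Stem-cell and breast cancer stem-like genes had a median of -0.063 (percentile 9.58), from ALDH1A3 (1.71-fold higher; 0.78 ± 0.21) and BMI1 (0.24 ± 0.21) to SOX2 (-0.31 ± 0.20) and CD44 (-0.41 ± 0.21). D-type cyclins, CDKs and CDK inhibitors had a median of -0.0053 (percentile 34.9; CDKN2D 0.38 ± 0.20, CCNG1 -0.45 ± 0.20). Hedgehog pathway genes had a median of -0.065 (percentile 15.5; GAS1 0.46 ± 0.32, PTCH1 -0.44 ± 0.37, or -0.086 with normexp) and Wnt target genes 0.0071 (percentile 38.4; SP5 0.61 ± 0.25, or 0.31 with normexp, RNF43 -0.59 ± 0.20).

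The epithelial, oestrogen response, luminal, basal and immune cell lists were also within the range. Endothelial markers, like the fibroblast markers above, had no percentile, and the mesenchymal list lay outside the range as given above. Epithelial genes had a median of 0.026 (percentile 57.98), with the plakoglobin gene JUP 1.61-fold higher (0.69 ± 0.20) and the tight junction gene TJP1 at -0.34 ± 0.20. Oestrogen response genes had a median of 0.072 (percentile 93.1), with the EGF receptor ligand gene AREG 1.78-fold higher (0.84 ± 0.20, 2 probes) and STC2 at -0.27 ± 0.20. Luminal identity genes had a median of -0.0062 (percentile 28.6; EHF 0.66 ± 0.21, MLPH -0.41 ± 0.20). Basal and myoepithelial genes had a median of -0.062 (percentile 11.6) with keratin genes on both sides, KRT17 at 0.89 ± 0.21 and KRT6B at -0.83 ± 0.20. Immune cell markers had a median of -0.084 (percentile 10.3; CD14 0.086 ± 0.21) with none at least 1.5-fold higher, and CD3E, a dim gene with 1 probe, stood at -3.09 ± 0.38, or -1.51 with normexp. Of 10 endothelial markers 4 were measured, with a median of -0.32 (VWF 0.032 ± 0.21, EMCN -0.67 ± 0.21).

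Among stress and metabolic lists, AP-1 and immediate-early genes had a median of 0.075 (percentile 88.8). FOSB, an AP-1 subunit gene, was 3.82-fold higher (1.93 ± 0.22) and FOS stood at 0.50 ± 0.20, while CCN2 (CTGF on the array) was 1.75-fold lower (-0.81 ± 0.23, or -0.34 with normexp). Heat shock and chaperone genes had a median of -0.0094 (percentile 27.1); the small heat shock protein gene CRYAB was 4.15-fold higher (2.05 ± 0.23, or 1.36 with normexp) and the HSP70 genes HSPA1A and HSPA1B stood at -0.67 ± 0.20 and -0.52 ± 0.20. The mTOR pathway median was -0.021 (percentile 27.9), with the mTOR inhibitor gene DEPTOR 1.86-fold higher (0.89 ± 0.20) and DDIT4 at -0.32 ± 0.20. Unfolded protein response and ATF4 genes had a median of -0.018 (percentile 19.3; DDIT3 0.43 ± 0.20, PHGDH -0.51 ± 0.20), NRF2 target genes -0.039 (percentile 11; GCLM 0.31 ± 0.20, ABCC3 -0.21 ± 0.20) and apoptosis regulator genes 0.046 (percentile 75.5; MCL1 0.39 ± 0.20, APAF1 -0.33 ± 0.26, or -0.11 with normexp). Oxidative phosphorylation genes had a median of 0.051 (percentile 78.1; COX6C 0.31 ± 0.20, UQCRB -0.45 ± 0.21 with its 2 probes at -0.85 and -0.049) and ribosomal protein genes 0.047 (percentile 68.1; RPL11 0.27 ± 0.20, RPS23 -0.31 ± 0.20 with its 2 probes at -0.55 and -0.060). Small-RNA silencing machinery genes had a median of -0.083 (percentile 6.15), with 11 of 14 below 0 and the dicer gene DICER1 at -0.43 ± 0.20. Housekeeping reference genes had a median of 0.0032 (percentile 36.4; RPLP0 0.46 ± 0.20 with its probes at 0.0016 and 0.91, TFRC -0.35 ± 0.20).

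Of the genes of prior interest, none reached 1.5-fold in the main setting. MYC was the furthest from 0, 1.40-fold lower (-0.49 ± 0.20, SD 0.051 over the 10 spots of its measured probe), but stood at -0.14 with no filter on background. CDKN1A (-0.39 ± 0.20) and JUN (-0.35 ± 0.20) were next. Scaled to spike-in RNA, MYC (-0.77), CDKN1A (-0.68) and JUN (-0.63) were over 1.5-fold lower, and the other genes of prior interest were not. KLF4, a pluripotency factor gene, stood at -0.23 ± 0.20 and CDK14, dim at intensities of 63.3 and 80.6, at -0.26 ± 0.24, or -0.095 with normexp. Published work on DYRK2 in this cell line may rest on these arrays, so KLF4 and CDK14 may not be independent evidence. The cyclin E1 gene CCNE1 (0.043 ± 0.20), the EMT factor gene SNAI1 (-0.0088 ± 0.21), the telomerase gene TERT (0.22 ± 0.21) and the E-cadherin gene CDH1 (0.051 ± 0.20) were within about 1 scanner error of 0. The oestrogen receptor gene ESR1 stood at 0.25 ± 0.20, with 3 probes between 0.0029 and 0.47.

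Some genes were well above background on 1 array only, and for these the fold is a bound against the lowest signal well above background on the other array, or the dim probe's own where that was higher. By the main detection call there were 658 such genes on the array labelled siDYRK2, 151 of them with a bound of at least 2-fold. On the array labelled siControl there were 903, 75 of them with such a bound. The median log2 bound was 0.70 for the 658 and 0.29 for the 903. Of the 903, 103 had a bound below 1-fold, and of the 658 none had. Relative to the 75th percentile, the lowest signal well above background was lower on the array labelled siControl. That tended to raise the bounds of the 658 against those of the 903, so 151 and 75 are not directly comparable. Another detection call of the scanner software, positive and significant over background, gave 1751 and 1971 genes in place of 658 and 903. On the array labelled siDYRK2 the largest bounds were those of STYXL2 (DUSP27 on the array; at least 16.9-fold), of COL1A2, the other collagen I chain gene (at least 14.5-fold; intensity 260 against 7.03), and of the matrix proteoglycan gene DCN (at least 13.9-fold). On the array labelled siControl they were those of the antisense RNA MAGI2-AS3 (at least 19.2-fold), of SPATA31F2P (FAM205B on the array; at least 10.9-fold) and of BANF2 (at least 8.41-fold).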

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

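The tests below were chosen after the results had been seen, except the interferon median without gene families and the mesenchymal median among brighter members. One signal came from control spots that the comparison does not use: 8 probes for the E1A spike-in control RNA were higher on the array labelled siDYRK2, with a median log2 difference of 0.28 (1.22-fold; 0.18 to 0.38, SD 0.067).

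DYRK2, the targeted gene, was not lower on the array labelled siDYRK2 by more than the scanner error after the main scaling. The tables argue against a fall of 1.5-fold or more hidden by scaling, since the lowest value over the scalings was -0.31. That value, from spike-in scaling, was beyond the scanner error, so a smaller fall is not argued against. The tables argue against a dim probe, since its control signal was 135 times the lowest signal well above background. They also argue against swapped labels with a knockdown that this probe reads, which needs DYRK2 higher on that array, where the difference was -0.031. With 1 DYRK2 probe on the array, a transcript that was not lost and a cleaved transcript whose probed part persisted cannot be told apart. Cells of another type under this label are argued against by 95.6% of 45 epithelial and luminal identity genes lying within 1.5-fold. This closeness was not particular to identity genes, since most of all 20662 genes lay within 1.5-fold too (quartiles of -0.12 and 0.18). Another MCF-7 sample under the label, and recovery of the transcript by the time of harvest, were not tested.

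Interferon-stimulated genes were higher on the array labelled siDYRK2. Scaling does not account for it, the lowest list median over the scalings being 0.53, nor do cross-hybridising families, since the 20 members outside the IFIT, IFI, OAS, IFITM and MX families had a median of 0.62. Immune cells are argued against by 0% of measured immune markers being at least 1.5-fold higher. Double-stranded RNA sensors are known, but cells of the array labelled siControl also received an siRNA, so a response common to duplexes would be shared. A response particular to the duplex against DYRK2 and an effect of losing DYRK2 cannot be told apart, because 1 array carried that duplex. DYRK2 RNA was not lower by more than the scanner error after the main scaling (-0.031), which does not decide between them. The first remains a hypothesis, and further duplexes against DYRK2 would be needed to test it.

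Mesenchymal genes, led by COL1A1, were higher on the array labelled siDYRK2, where COL1A2, DCN and THY1 were detected and not on the other. A first criterion for fibroblasts, the number of markers detected, left the question open at 5 of 12. A second, set after those values had been seen, asked for COL3A1, SPARC, FN1, LUM, FBN1, MMP2 and POSTN. Of these 7 abundant fibroblast genes, 0 were detected on the array labelled siDYRK2 and at least 1.5-fold higher. Because the 7 were picked after the values had been seen, this cannot decide, and fibroblast RNA remains open. Scalings that kept the median of all genes in place left the list at 0.17 or above, over the 0.15 that bounds the random lists in the main setting. For scalings that shift every difference alike, this outcome was fixed in advance, since the rule admitted only small shifts. Random lists would shift with them too, so those scalings are no check here. Spike-in scaling, which this rule left out, put the list at -0.020. Noise near background cannot be told apart from a real difference, since the 7 brighter members had a median of 0.25, between the bounds set for either reading, and none was 1.5-fold higher. Other mesenchymal RNA, and a response of the cells, may also account for it and were not tested.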

How the results depend on the processing

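All alternatives here were planned; no paired analysis was possible because each group had 1 array. Of the values for the comparison's main results, 501 were counted as kept, 40 as moved and 8 as reversed. The size of a list median was judged relative to the shift of the shared genes. Spike-in scaling, which took the NF-kB median to 0.090 and the p53 target median to -0.51, could thus leave a list counted as kept. Medians of lists within the random range could also change sign without being counted as reversed. With spike-in scaling the DYRK and HIPK family went from 0.069 to -0.21 and oestrogen response genes from 0.072 to -0.21. The cause of a change was not tested unless stated. Signal over background limits the dim genes most. Genes at least 2-fold higher and lower numbered 30 and 9 with normexp, 46 and 162 with spike-in scaling, 1427 and 887 with no filter on background (more, dimmer genes) and 20 and 6 among brighter probes (fewer genes). In place of the genes at least 2-fold higher, 664 were at least 1.5-fold and 24 at least 3-fold higher; in place of the genes at least 2-fold lower, 300 and 15. With another detection call, 1751 genes were detected on siDYRK2 only and 1971 on siControl only. Spike-in scaling lowered the median of all genes by 0.28, by construction, and with it DYRK2 to -0.31. The list medians counted as reversed there were -0.020 (mesenchymal), -0.069 (histones), -0.13 (G2/M), -0.14 (proteasome), -0.16 (cholesterol), -0.17 (MYC targets) and -0.18 (G1/S). Each was still above the random range, which moved down with it.

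Other list medians moved as follows. With normexp, interferon 0.67, fibroblast 1.13, endothelial -0.17, immune -0.016 and glycolysis -0.031. With no filter on background, fibroblast 0.95, mesenchymal 0.33, AP-1 0.17 (percentile 99.7, now above the range), endothelial 0.14, basal 0.034 and glycolysis -0.035, while CXCL8 reversed to -0.38. Among brighter probes, AP-1 -0.013, DYRK and HIPK family -0.031, Wnt -0.077, basal -0.14 (percentile 2.44, now below the range) and Hedgehog -0.16, with glycolysis reversed to 0.031. With the brightest probe per gene, interferon 0.71, Hedgehog 0.017, DYRK and HIPK family -0.018, glycolysis -0.038 and basal -0.13 (percentile 2.20, below the range); with the median over probes, Hedgehog 0.017 and glycolysis -0.027. Without shared members, luminal -0.085 and fibroblast 1.40. Fibroblast, immune and endothelial markers had no value among brighter probes, and Hedgehog no percentile. Glycolysis fell within the random range in 5 alternatives, and the other 10 lists called outside it stayed there in each. Scaling by the median, by detected probes or by spike-in RNA, and the unscaled values, shifted every difference by a constant. Those settings could not change a list's place among random lists, so they are no check of it.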

Other observations

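The lists in this part were chosen after values of some of their members had been seen, so their percentiles are descriptions and not independent evidence. Antigen presentation genes, which interferons are known to induce, had a median of 0.18 over 16 members (percentile 99.93), with 11 above 0; HLA-B stood at 0.49 ± 0.21 and the peptide-trimming enzyme gene ERAP1 at -0.26 ± 0.20. Kallikrein genes, a cluster of secreted serine protease genes on chromosome 19, were lower: 9 of 10 measured members were below 0, with a median of -0.27 (percentile 0.080). KLK11, a bright gene (intensity 9467 against 16285), was 1.62-fold lower (-0.70 ± 0.20), and KLK10, a dim one, 1.81-fold lower (-0.86 ± 0.30). The 5 measured EGF receptor ligand genes were all above 0, with a median of 0.27 (percentile 95.4, within the random range); HBEGF stood at 0.86 ± 0.22 and AREG at 0.84.

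Other added lists lay within the random range. IGF-binding protein genes had a median of 0.12 (percentile 85.2), with IGFBP3 1.86-fold higher (0.89 ± 0.20). A wider set of fibroblast and matrix genes had a median of 0.10 over 23 members (percentile 88.4), from COL12A1 (-0.44) to PCOLCE, which encodes an enhancer of procollagen processing (0.85). Cathepsin and lysosomal enzyme genes had a median of -0.0014 (percentile 37.9), although CTSB and CTSO were each 1.76-fold lower (both -0.82 ± 0.20). By RefSeq class, the medians were 0.031 for 203 small nucleolar RNAs (percentile 48.9), 0.037 for 797 long non-coding RNAs (46.0), 0.13 for 17 small nuclear RNAs (97.3) and 0.038 for 402 transcribed pseudogenes (77.7). The repeated SNAR family carried the small nuclear RNA median: 9 of its 10 members were above 0 (median 0.34), whereas 5 of the 7 others were below 0 (median -0.11). Probes for repeated copies may share targets, so the SNAR members may not be separate observations.

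Among dim genes outside the naming rule, singled out after their values were seen, DPYSL3, a cytoskeletal regulator gene, was 9.54-fold higher on the array labelled siDYRK2 (intensity 246 against 27.4; 3.25 ± 0.33) and AEBP1, a matrix protein gene, 5.39-fold higher (519 against 102; 2.43 ± 0.22). Each rested on 1 probe.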
